A study of Mus musculus with 18 samples.

How the data were processed

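The series compares small intestinal crypt cells sorted by fluorescence, and 6 of its 18 samples were analysed here, the 2 arrays each of the reporter-negative, reporter-low and reporter-high gates. The columns of the other 12 samples, from a lineage-tracing line, hold no values in the file used here, so those samples, the comparisons within that line, the comparisons between the lines and the fit over all 18 arrays are not analysed here. Groups and replicate numbers came from the sample titles. RNA was extracted with a column kit with DNase treatment, amplified with a whole-transcript kit and labelled with biotin, per the labels' protocols. Values were made by the authors with Affymetrix Expression Console 1.3.0.187 and RMA, per the submitters' processing notes. The deposited values range from about 1.9 to 14.0 and were taken as log2 values; the authors' background and summarisation options are not given in the sources used here. RMA compresses differences near the floor and near the ceiling of the signal. No scanner files or detection calls were used here, so a background level was the only guide to low signal.

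The array holds 35556 probe sets. The platform annotation gave 21789 a single gene symbol, 1621 several symbols, and did not list 12146. Of the single-symbol probe sets, 21698 matched a gene ID of the GRCm38.p6 gene table, which was used for names only, and 91 kept the array's symbol. For the 999 genes with more than 1 probe set, the probe set with the highest mean was used, which left 19938 genes. The background level, 4.23 on the log2 scale, was the 95th percentile of mean values over 1207 olfactory, vomeronasal and trace amine receptor genes on the 6 filled arrays. It was planned over all 18. Of the genes, 12891 lay above it on average. A named gene with no array of its dimmer gate above it is given as at least the change against that level, a rule added after the data were examined.

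Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the deposited log2 values, with the 6 arrays in a single fit of 3 group means, a shared estimate of the spread and 3 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 19938 genes, and genes with an adjusted p under 0.05 were called. Standard errors of log2 changes are those of limma. The labels describe each array as a pool of 2 animals and do not say whether gates shared pools. The p-values therefore measure only the spread between the 2 arrays of a gate, pooled over all gates.

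Gene lists of crypt cell types, of other cell types the sort could hold and of pathways were fixed before the data were examined. Lists with at least 5 measured members, 23 in each comparison, were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. At the preset value 15 lists passed in low against negative, 12 in high against negative and 11 in high against low cells, and with the estimated correlation 3, 0 and 1. These losses do not reflect the correlation value alone, since lists with an estimate at or below the preset value also lost their calls. A symbol that matched an unrelated gene through a synonym was left out of the hormone list after the data were examined.

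The named genes were Cfap126, 12 landmark genes of crypt cell types, the 6 largest increases and the 6 largest decreases among called genes above background with groups that did not overlap (predicted genes left out), and up to 4 members with the smallest p of each list that passed or is discussed. Ptprc, Slc14a1, Slc12a2, Vdr, Rnf43, Nkd1 and Cdk6 come from these lists. Egr1, Nrarp, Vdr in high cells and the genes of lists chosen after the data were examined fall outside this rule and were chosen after their values were seen. Alternatives were fixed before the data were examined and covered the prior, the arrays in the fit, a filter on dim genes, the probe set rule, the scaling, array weights, the thresholds, the replicate number as a block and leaving out each array.

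The tests were tried on simulated data for the same 19938 genes, with 200 genes changed. In low against negative, 16.0% of genes changed 2-fold and 94.0% of genes changed 4-fold were recovered, in high against negative 15.0% and 96.0%, and in high against low 18.0% and 95.0%. In these simulations most changes of 2-fold stayed below the threshold. More genes were called in the data, where the adjusted threshold is therefore less strict, so this recovery does not carry over. The smallest absolute log2 changes called in the data were 0.79, 0.82 and 0.81 in the same order. Both shifted lists and 0 of 18 unshifted lists were called by camera in each comparison. The simulated genes varied independently, so these calls do not test lists whose members vary together. In the data the estimated correlation of a list ranged from -0.03 (stem cell markers) to 0.69 (enterocyte genes). Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.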

Results

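Gene expression was measured on 1-colour microarrays in mouse small intestinal crypt cells sorted by the brightness of a fluorescent reporter for Flattop (gene symbol Cfap126), a gene of the planar cell polarity pathway. The crypts came from 4-month-old C57Bl6/J mice that carried 1 reporter allele, and the cells were separated into reporter-negative, reporter-low and reporter-high gates. Each gate had 2 arrays, and each array held RNA from a pool of 2 animals. The labels do not say whether the gates of 1 replicate number came from the same animals. The comparisons ask which crypt cell programmes accompany low and high reporter signal. The median RMA value of the 6 arrays lay between 4.54 and 4.74 on the log2 scale. The reporter-high pair was the least alike, with a Pearson correlation across genes of 0.946 against 0.981 for the negative pair and 0.975 for the low pair. On reporter-high replicate 2, 69.6% of genes lay above the background level, against 61.4% to 65.6% on the other arrays. The number of arrays limits the precision of every value.

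The Flattop transcript itself showed no called difference between gates. Cfap126 averaged 5.09 ± 0.42 (SD, n = 2) in the negative gate, 5.64 ± 0.69 in the low gate and 5.07 ± 0.11 in the high gate. The difference between high and negative was -0.01 ± 0.36 (SE; limma adjusted p = 0.983), with a 95% interval from -0.86 to 0.83. Low minus negative was 0.55 ± 0.36 (limma adjusted p = 0.528).

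**Figure D1:**
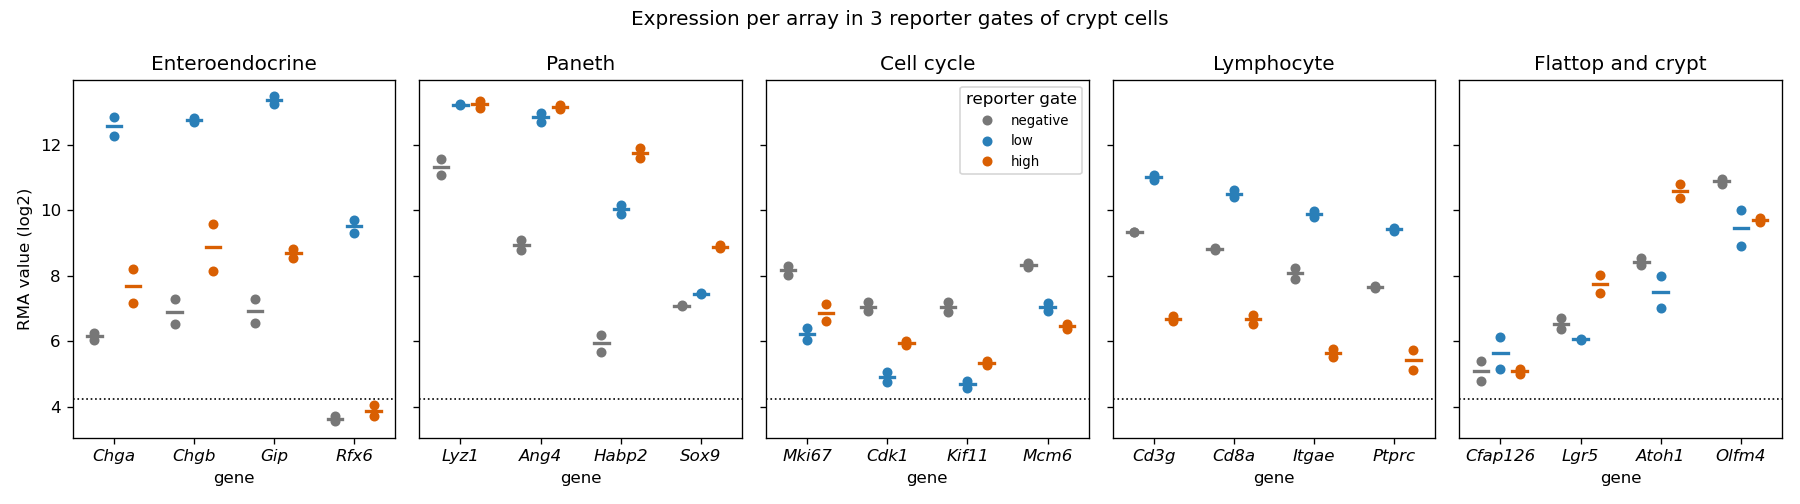
RMA values (log2, vertical axis) of 20 genes on each of the 6 arrays, as points, with the gate mean as a bar; the dotted line is the background level of 4.23. Chga and Chgb stood highest in the low gate, Habp2 and Sox9 in the high gate, and the Cfap126 values of the negative gate overlapped those of both other gates.

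Cells with low reporter signal carried an enteroendocrine profile. Chga and Chgb, granins of hormone-storing granules, rose 85.0-fold and 57.8-fold over the negative gate. Chga averaged 12.55 ± 0.42 (SD, n = 2) in low cells and 6.14 ± 0.16 in negative cells (limma adjusted p = 0.000455). The hormone genes Pyy (peptide YY), Cck (cholecystokinin) and Gip rose by 6.73 ± 0.42, 6.72 ± 0.74 and 6.43 ± 0.28 on the log2 scale (SE), with Cck above background on 1 of 2 negative arrays. Nts (neurotensin), Afp, which encodes alpha-fetoprotein, and Cpe, the carboxypeptidase that trims prohormones, were not above background in negative cells and rose by at least 6.99, 7.41 and 6.97. In all, 1188 of 19938 genes differed between low and negative cells, 681 higher and 507 lower, or 577 higher and 586 lower with arrays centred on their medians.

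Of 31 pan-enteroendocrine genes, 30 rose, and 30 rose when adjusted over the list alone (camera adjusted p = 1.26e-46, and adjusted p = 0.0317 with an estimated correlation). The prohormone convertase gene Pcsk1 rose by 5.08 ± 0.26, and Scg2, not above background in negative cells, by at least 5.33. Of 17 gut hormone genes, 12 rose, also 12 adjusted over the list alone (camera adjusted p = 2.47e-15, and adjusted p = 0.0374 with an estimated correlation). Gcg and Sst rose by 6.38 ± 0.32 and 5.72 ± 0.34. Of 22 enteroendocrine transcription factor genes, 13 rose, also 13 adjusted over the list alone (camera adjusted p = 9.71e-20, and adjusted p = 0.0374 with an estimated correlation). Rfx6, Peg3 and Neurod1, not above background in negative cells, rose by at least 5.27, 5.18 and 4.68, and Pax6, above it on 1 of 2 negative arrays, by 4.24 ± 0.23. Neurog3, the transient inducer of the lineage, differed by 0.52 ± 0.41 (adjusted p = 0.639).

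Some Paneth genes also rose in low cells. Of 21 Paneth genes, 11 rose, or 14 adjusted over the list alone (camera adjusted p = 2.47e-15, but adjusted p = 0.146 with an estimated correlation). Clps, Habp2, Ang4 and Itln1 rose by 4.27 ± 0.38, 4.09 ± 0.24, 3.89 ± 0.21 and 2.87 ± 0.23, and the lysozyme gene Lyz1 rose 3.71-fold (adjusted p = 0.00606). The call of Lyz1 was lost without negative replicate 2 (adjusted p = 0.0562). Called Paneth genes numbered 7 (without negative replicate 1), 6 (without negative replicate 2), 7 (without low replicate 1) and 6 (without low replicate 2). Sox9 differed by 0.37 ± 0.17 (adjusted p = 0.342).

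Some proliferation genes fell in low cells. Of 39 cell cycle genes, 25 fell, or 35 adjusted over the list alone (camera adjusted p = 2.99e-28, but adjusted p = 0.0542 with an estimated correlation). Kif11, Nusap1, Cdk1 and Aurka fell by 2.37 ± 0.20, 2.20 ± 0.24, 2.15 ± 0.21 and 1.97 ± 0.21, and Mki67 fell by 1.95 ± 0.25. Of 22 stem cell markers, 4 fell (Slc14a1, Slc12a2, Vdr and Rnf43), or 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 4.13e-05, but adjusted p = 0.0592 with an estimated correlation). Lgr5 differed by -0.49 ± 0.25 (adjusted p = 0.38) and Olfm4 by -1.42 ± 0.34 (adjusted p = 0.0649). Of 23 nuclear genes of the respiratory chain, 4 fell, or 13 adjusted over the list alone (camera adjusted p = 1.74e-10, but adjusted p = 0.0592 with an estimated correlation). Uqcrc1 and Cox5a fell by 1.45 ± 0.23 and 1.38 ± 0.22. Of 33 enterocyte genes, 8 fell, or 11 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.37e-06, but adjusted p = 0.441 with an estimated correlation). Of 16 Notch pathway genes, Hes1 and Nrarp fell, the first by 2.06 ± 0.26, or 2 were higher and 3 lower adjusted over the list alone, and the list did not pass (camera adjusted p = 0.467). The calls of Nusap1, Mki67, Slc14a1, Slc12a2, Vdr, Rnf43, Uqcrc1, Cox5a and Nrarp were lost without negative replicate 1 (adjusted p from 0.0649 to 0.248). The calls of Nusap1, Aurka, Mki67, Slc14a1, Slc12a2, Vdr, Rnf43, Uqcrc1, Cox5a, Hes1 and Nrarp were lost without negative replicate 2 (adjusted p from 0.051 to 0.201). The calls of Slc12a2, Rnf43, Uqcrc1 and Nrarp were lost without low replicate 1 (adjusted p from 0.0533 to 0.179). The calls of Mki67, Slc14a1, Slc12a2, Vdr, Rnf43, Uqcrc1, Cox5a, Hes1 and Nrarp were lost without low replicate 2 (adjusted p from 0.0514 to 0.202). Rnf43 also lost its call in 3 alternative fits (adjusted p from 0.0521 to 0.0639). Nrarp also lost its call in 1 alternative fit (adjusted p = 0.0667). Without either negative array most cell cycle calls and all stem cell, respiratory chain and enterocyte calls were lost. Without either low array fewer cell cycle, stem cell, respiratory chain, enterocyte and Notch genes were called. Without low replicate 1 a stem cell marker was called higher, beside others called lower.

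Some transcripts of immune cells moved with the gate. Of 21 lymphocyte genes, 9 rose and 2 fell in low cells, or 14 and 3 adjusted over the list alone (camera adjusted p = 2.16e-05, but adjusted p = 0.292 with an estimated correlation). The T cell genes Itgae, Cd8a and Cd3g rose by 1.80 ± 0.21, 1.69 ± 0.19 and 1.68 ± 0.18. Of 20 myeloid and mast cell genes, 7 rose and 3 fell in low cells, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.00439, but adjusted p = 0.292 with an estimated correlation). Fcer1g and Tyrobp, signalling adaptors of natural killer and myeloid cells, rose by 2.27 ± 0.25 and 2.31 ± 0.27. In high cells 0 of these 20 rose and 6 fell, or 1 and 6 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.135). In contrast, the plasma cell genes Igkv10-96 and Jchain, not above background in low cells, fell by at least 2.65 and 2.76, and the mast cell protease genes Mcpt1 and Mcpt2 fell by 3.06 ± 0.41 and 2.92 ± 0.39. Reg3a and the potassium channel gene Kcnn4 fell by 3.29 ± 0.49 and 3.10 ± 0.17. Mcpt1 and Reg3a were above background on 1 of 2 low arrays. The calls of Itgae, Cd8a, Cd3g, Fcer1g, Tyrobp, Mcpt1, Mcpt2 and Reg3a were lost without negative replicate 1 (adjusted p from 0.0572 to 0.11). The calls of Cd8a, Cd3g, Tyrobp, Mcpt1, Mcpt2 and Reg3a were lost without negative replicate 2 (adjusted p from 0.0517 to 0.0861). The call of Reg3a was lost without low replicate 2 (adjusted p = 0.0743). Fewer lymphocyte and myeloid genes were called in low cells whichever of these arrays was left out. Without negative replicate 1 no lymphocyte gene stayed called higher, the lymphocyte call that was left was a decrease, and no myeloid gene was called. Without negative replicate 2 most of the lymphocyte increases also lost their calls. Called myeloid genes numbered for high against negative cells 0 (without negative replicate 1), 0 (without negative replicate 2), 5 (without high replicate 1) and 5 (without high replicate 2).

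A minority of the genes that cell dissociation induces changed in low cells. Of 27 immediate early and heat shock genes, 4 rose (Btg2, Egr2, Fosb and Egr1) and Ier3 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 4.47e-05, but adjusted p = 0.292 with an estimated correlation). Btg2, Egr2 and Fosb rose by 1.43 ± 0.20, 1.32 ± 0.19 and 1.15 ± 0.23. The calls of Btg2, Egr2, Fosb, Egr1 and Ier3 were lost without negative replicate 1 (adjusted p from 0.0919 to 0.24), negative replicate 2 (adjusted p from 0.0691 to 0.284) or low replicate 2 (adjusted p from 0.0777 to 0.25). The calls of Egr2, Fosb, Egr1 and Ier3 were lost without low replicate 1 (adjusted p from 0.0533 to 0.228). Fosb also lost its call in 1 alternative fit (adjusted p = 0.0509). Egr1 also lost its call in 4 alternative fits (adjusted p from 0.0561 to 0.0792). Ier3 also lost its call in 4 alternative fits (adjusted p from 0.0506 to 0.101). Called dissociation genes numbered 0 (without negative replicate 1), 0 (without negative replicate 2), 1 (without low replicate 1) and 0 (without low replicate 2). For high against negative cells 2 rose and 1 fell, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.719). Called dissociation genes numbered there 0 (without negative replicate 1), 0 (without negative replicate 2), 5 (without high replicate 1) and 4 (without high replicate 2).

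All 1188 genes called between low and negative cells had arrays of the groups that did not overlap, as did 51.5% of all genes, where chance gives 33.3%. Without a single array the count was 187 (negative replicate 1), 197 (negative replicate 2), 565 (low replicate 1) and 417 (low replicate 2), and with array weights it was 2150. Of 78 named genes called, 47, 45, 20 and 32 lost the call in that order, while Chga, Chgb and Nts passed without any of these arrays.

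Paneth genes were among the largest increases in cells with high reporter signal. The Paneth genes Habp2, Clps, Nupr1 and Ang4 rose by 5.82 ± 0.24, 5.22 ± 0.38, 4.99 ± 0.44 and 4.21 ± 0.21 over the negative gate, and Lyz1 rose 3.73-fold (limma adjusted p = 0.0131). Pnliprp2, a lipase gene, rose by 6.64 ± 0.33, the gastrin gene Gast by 6.95 ± 0.91 and the iron reductase gene Cybrd1, above background on 1 of 2 negative arrays, by 4.88 ± 0.53. Lyz1 averaged 13.23 ± 0.14 (SD, n = 2) in high cells and 11.33 ± 0.34 in negative cells. In all, 939 of 19938 genes differed, 272 higher and 667 lower, and quantile normalization of the gene values gave 324 higher and 297 lower. The calls of Lyz1, Gast and Cybrd1 were lost without negative replicate 1 (adjusted p from 0.087 to 0.117) or negative replicate 2 (adjusted p from 0.119 to 0.14).

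Of 21 Paneth genes, 13 rose in high cells, or 18 adjusted over the list alone (camera adjusted p = 6.36e-18, but adjusted p = 0.155 with an estimated correlation). Itln1 and Sox9 rose by 3.04 ± 0.23 and 1.80 ± 0.17. Atoh1, the master regulator of secretory cells, rose by 2.16 ± 0.34 and Bhlha15, which drives secretory cell maturation, by 3.94 ± 0.24. Of 16 early secretory genes, 2 were higher and 1 lower, or 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0322, but adjusted p = 0.263 with an estimated correlation). This list test was lost without high replicate 1 (adjusted p = 0.246). The lower gene was Rgs2. Called early secretory genes numbered 1 (without negative replicate 1), 1 (without negative replicate 2), 3 (without high replicate 1) and 2 (without high replicate 2). The call of Rgs2 was lost without negative replicate 1 (adjusted p = 0.145) or negative replicate 2 (adjusted p = 0.162). In low cells Bhlha15 rose by 2.02 (adjusted p = 0.00618) and Rgs2 by 2.47 (adjusted p = 0.00461), or 2 genes were higher and 1 lower adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0951). Those 2 calls were lost without negative replicate 1 (adjusted p = 0.0691 and 0.0589) or negative replicate 2 (adjusted p = 0.0665 and 0.051). Of 28 endoplasmic reticulum and unfolded protein response genes, 7 rose, or 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000412, but adjusted p = 0.309 with an estimated correlation). Ern1, Herpud1 and Dnajb9 rose by 1.78 ± 0.19, 1.63 ± 0.23 and 1.43 ± 0.21. The list test was lost without high replicate 1 (adjusted p = 0.0815). In low cells Herpud1, Ern1 and Dnajb9 of this list also rose, the first by 1.23 ± 0.23 and the second by 0.96 ± 0.19, or 4 genes adjusted over the list alone (camera adjusted p = 0.0014, but adjusted p = 0.328 with an estimated correlation). Of 22 stem cell markers, Lgr5 and Nkd1 rose and Slc14a1, Vdr and Cdk6 fell, or 4 rose and 5 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.179). Slc14a1 fell by 2.20 ± 0.23. Lgr5 rose by 1.21 ± 0.25 (adjusted p = 0.0447). The calls of Itln1, Sox9, Atoh1, Ern1, Herpud1, Dnajb9, Lgr5, Nkd1, Slc14a1, Vdr and Cdk6 were lost without negative replicate 1 (adjusted p from 0.0855 to 0.259) or negative replicate 2 (adjusted p from 0.0751 to 0.218). The calls of Vdr and Cdk6 were lost without high replicate 1 (adjusted p = 0.0551 and 0.0547). The calls of Atoh1, Lgr5, Nkd1, Vdr and Cdk6 were lost without high replicate 2 (adjusted p from 0.0629 to 0.108). Lgr5 also lost its call in 3 alternative fits (adjusted p from 0.0583 to 0.0853). Nkd1 also lost its call in 1 alternative fit (adjusted p = 0.0675). Vdr also lost its call in 3 alternative fits (adjusted p from 0.0552 to 0.126). Cdk6 also lost its call in 5 alternative fits (adjusted p from 0.052 to 0.101). Called Paneth, endoplasmic reticulum and stem cell genes numbered 5, 0 and 0 (without negative replicate 1), 4, 0 and 0 (without negative replicate 2), 15, 8 and 3 (without high replicate 1) and 15, 5 and 1 (without high replicate 2). In low against negative cells the calls of Herpud1, Ern1 and Dnajb9 were lost without negative replicate 1 (adjusted p from 0.199 to 0.215), negative replicate 2 (adjusted p from 0.122 to 0.214) or low replicate 2 (adjusted p from 0.134 to 0.179). In low against negative cells the calls of Ern1 and Dnajb9 were lost without low replicate 1 (adjusted p = 0.134 and 0.193). There Ern1 also lost its call in 2 alternative fits (adjusted p = 0.0509 and 0.0786). There Dnajb9 also lost its call in 2 alternative fits (adjusted p = 0.0604 and 0.0665). Called endoplasmic reticulum genes numbered in that comparison 0 (without negative replicate 1), 0 (without negative replicate 2), 1 (without low replicate 1) and 0 (without low replicate 2).

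Some hormone genes also rose in high cells. Of 17, 4 rose (Gast, Ghrl, Gip and Sst), or 7 adjusted over the list alone (camera adjusted p = 0.000157, but adjusted p = 0.148 with an estimated correlation). Ghrl rose by 4.08 ± 0.63 and Sst by 2.11 ± 0.34. Of 31 pan-enteroendocrine genes, Ptprn2 rose and Ddc fell, or 10 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000198, but adjusted p = 0.164 with an estimated correlation). Chga differed by 1.55 ± 0.37 (adjusted p = 0.0678). The calls of Gast, Ghrl, Gip, Sst, Ptprn2 and Ddc were lost without negative replicate 1 (adjusted p from 0.0993 to 0.155) or negative replicate 2 (adjusted p from 0.0795 to 0.166). The calls of Gip and Sst were lost without high replicate 2 (adjusted p = 0.0661 and 0.07). Ddc also lost its call in 1 alternative fit (adjusted p = 0.0536). Called hormone and pan-enteroendocrine genes numbered 0 and 0 (without negative replicate 1), 0 and 0 (without negative replicate 2), 6 and 4 (without high replicate 1) and 3 and 8 (without high replicate 2).

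Some proliferation, absorptive and immune genes fell in high cells. Of 39 cell cycle genes, 21 fell, or 34 adjusted over the list alone (camera adjusted p = 2.06e-22, but adjusted p = 0.148 with an estimated correlation). Prc1, Mcm6 and Tpx2 fell by 1.91 ± 0.26, 1.86 ± 0.19 and 1.73 ± 0.20. Prc1 and Mcpt2 were above background on 1 of 2 high arrays. Of 33 enterocyte genes, 11 fell, or 24 adjusted over the list alone (camera adjusted p = 6.65e-16, but adjusted p = 0.295 with an estimated correlation). Slc15a1 and Krt20 fell by 2.04 ± 0.28 and 1.70 ± 0.22. Enterocyte genes were lower on replicate 2 than on replicate 1 in all 3 gates, by a median of 0.28, 0.83 and 0.45 for negative, low and high. Of 21 lymphocyte genes, 13 fell, or 16 adjusted over the list alone (camera adjusted p = 1.96e-16, but adjusted p = 0.148 with an estimated correlation). Nkg7 and Cd3g fell by 3.16 ± 0.40 and 2.63 ± 0.18, Jchain, not above background in high cells, by at least 2.76, Mcpt2 by 3.57 ± 0.39 and the carboxylesterase gene Ces1f by 3.25 ± 0.45. Of 23 respiratory chain genes, 6 fell, or 16 adjusted over the list alone (camera adjusted p = 1.38e-12, but adjusted p = 0.148 with an estimated correlation). Atp5c1, Cox4i1, Uqcrc1 and Atp5o of this list lost their calls after quantile normalization of the gene values (limma adjusted p from 0.0672 to 0.131). The calls of Prc1, Mcm6, Tpx2, Slc15a1, Krt20, Nkg7, Cd3g, Mcpt2 and Ces1f were lost without negative replicate 1 (adjusted p from 0.07 to 0.137) or negative replicate 2 (adjusted p from 0.0637 to 0.14). The call of Ces1f was lost without high replicate 2 (adjusted p = 0.0515). Called cell cycle, enterocyte, lymphocyte and respiratory chain genes numbered 0, 0, 1 and 0 (without negative replicate 1), 0, 0, 1 and 0 (without negative replicate 2), 23, 15, 11 and 12 (without high replicate 1) and 9, 4, 11 and 1 (without high replicate 2).

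Without a single array the count for high against negative was 15 (negative replicate 1), 13 (negative replicate 2), 1919 (high replicate 1) and 715 (high replicate 2), and it was 561 with only the groups compared, 620 with array weights and 621 after quantile normalization. Of 61 named genes called, 54, 54, 2 and 18 lost the call in that order, while Habp2, Clps and Pnliprp2 passed without any of these arrays. All 939 called genes had groups that did not overlap, as did 55.2% of all genes, where chance gives 33.3%.

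High and low cells differed in 978 of 19938 genes, 202 higher and 776 lower in high cells, or 326 higher and 616 lower after quantile normalization of the gene values. Nts, Afp, Tac1 and Gcg were lower in high cells by 7.08 ± 0.28, 7.04 ± 0.32, 5.85 ± 0.63 and 5.60 ± 0.32 on the log2 scale, with Nts and Afp above background on 1 of 2 high arrays. Rfx6, not above background in high cells, was lower by at least 5.27. Cybrd1, Atoh1 and Copz2 were higher by 3.34 ± 0.53, 3.09 ± 0.34 and 2.71 ± 0.36 (limma adjusted p = 0.018, 0.00512 and 0.00933). Lgr5 was higher in high cells by 1.70 ± 0.25 (adjusted p = 0.0134). The calls of Copz2 and Lgr5 were lost without low replicate 1 (adjusted p = 0.0633 and 0.0797). The call of Lgr5 was lost without low replicate 2 (adjusted p = 0.0801). The call of Cybrd1 was lost without high replicate 1 (adjusted p = 0.0516) or high replicate 2 (adjusted p = 0.0581). Cybrd1 also lost its call in 1 alternative fit (adjusted p = 0.052).

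Of 31 pan-enteroendocrine genes, 28 were lower in high cells, or 30 adjusted over the list alone (camera adjusted p = 8.61e-37, and adjusted p = 0.0451 with an estimated correlation). Of 17 hormone genes, 10 were lower, or 11 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.29e-08, but adjusted p = 0.0926 with an estimated correlation). Of 22 enteroendocrine transcription factors, 11 were lower, or 15 adjusted over the list alone (camera adjusted p = 8.19e-15, but adjusted p = 0.0666 with an estimated correlation). Of 21 Paneth genes, Sox9, Copz2 and Habp2 were higher by 1.44 ± 0.17, 2.71 ± 0.36 and 1.73 ± 0.24, or 6 adjusted over the list alone (camera adjusted p = 0.00102, lost without high replicate 1 with an adjusted p = 0.205, and adjusted p = 0.524 with an estimated correlation). Lyz1 differed by 0.01 ± 0.22 (adjusted p = 0.984). Of 21 lymphocyte genes, 14 were lower, or 15 adjusted over the list alone (camera adjusted p = 7.2e-17, but adjusted p = 0.153 with an estimated correlation). Cd3g, Itgae and Ptprc were lower by 4.31 ± 0.18, 4.23 ± 0.21 and 4.00 ± 0.24. Without a single array the count was 390 (low replicate 1), 381 (low replicate 2), 1739 (high replicate 1) and 748 (high replicate 2), and it was 499 with only the groups compared and 607 with array weights. Of 61 named genes called, 22, 23, 7 and 9 lost the call in that order. The calls of Sox9, Copz2 and Habp2 were lost without low replicate 1 (adjusted p from 0.0539 to 0.0838). The calls of Sox9 and Habp2 were lost without low replicate 2 (adjusted p = 0.0534 and 0.054). Fewer Paneth genes were called without low replicate 2 and none without low replicate 1. More were called without either high array, where a Paneth gene was also called lower without high replicate 1.

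Other lists also passed at the preset correlation alone. In high against low cells: of 20 myeloid genes, 6 were lower, or 6 lower adjusted over the list alone (camera adjusted p = 9.43e-05, but adjusted p = 0.246 with an estimated correlation). Of 27 dissociation genes, 3 were lower, or 4 lower adjusted over the list alone (camera adjusted p = 0.0028, but adjusted p = 0.524 with an estimated correlation). This list test was lost without low replicate 2 (adjusted p = 0.07) or high replicate 2 (adjusted p = 0.0748). Of 22 stem cell genes, 3 were higher, or 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.021, but adjusted p = 0.246 with an estimated correlation). This list test was lost without low replicate 2 (adjusted p = 0.0529) or high replicate 1 (adjusted p = 0.0537). Of 20 goblet cell genes, 3 were higher, or 3 higher adjusted over the list alone (camera adjusted p = 0.0014, but adjusted p = 0.365 with an estimated correlation). Of 33 enterocyte genes, 4 were lower, or 6 lower adjusted over the list alone (camera adjusted p = 0.00201, but adjusted p = 0.684 with an estimated correlation). This list test was lost without low replicate 1 (adjusted p = 0.788) or high replicate 2 (adjusted p = 0.169). Of 23 canonical Wnt genes, 4 were higher and 1 lower, or 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0414, but adjusted p = 0.365 with an estimated correlation). This list test was lost without low replicate 1 (adjusted p = 0.121), low replicate 2 (adjusted p = 0.0671) or high replicate 1 (adjusted p = 0.0754). Fewer members of each of these lists were called without either low array, and without a high array the numbers moved in both directions. Without low replicate 1 the stem cell and canonical Wnt members still called were lower in high cells, and none was called higher. Without low replicate 2 no stem cell gene was called, and the canonical Wnt members still called were lower. In low against negative cells: of 20 goblet cell genes, 1 was higher and 3 lower, or 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0206, but adjusted p = 0.336 with an estimated correlation). This list test was lost without negative replicate 1 (adjusted p = 0.0538) or low replicate 1 (adjusted p = 0.175). Of 22 ribosome biogenesis genes, 2 were lower, or 2 lower adjusted over the list alone (camera adjusted p = 6.92e-06, but adjusted p = 0.0592 with an estimated correlation). Called goblet cell and ribosome biogenesis genes numbered 0 and 0 (without negative replicate 1), 1 and 0 (without negative replicate 2), 1 and 1 (without low replicate 1) and 1 and 0 (without low replicate 2). In high against negative cells: of 22 enteroendocrine transcription factor genes, 1 was higher, or 4 higher adjusted over the list alone (camera adjusted p = 0.0114, but adjusted p = 0.238 with an estimated correlation). Of 22 ribosome biogenesis genes, 2 were lower, or 4 lower adjusted over the list alone (camera adjusted p = 0.000412, but adjusted p = 0.148 with an estimated correlation). Called enteroendocrine transcription factor and ribosome biogenesis genes numbered 0 and 0 (without negative replicate 1), 0 and 0 (without negative replicate 2), 2 and 4 (without high replicate 1) and 1 and 1 (without high replicate 2).

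**Figure D2:**
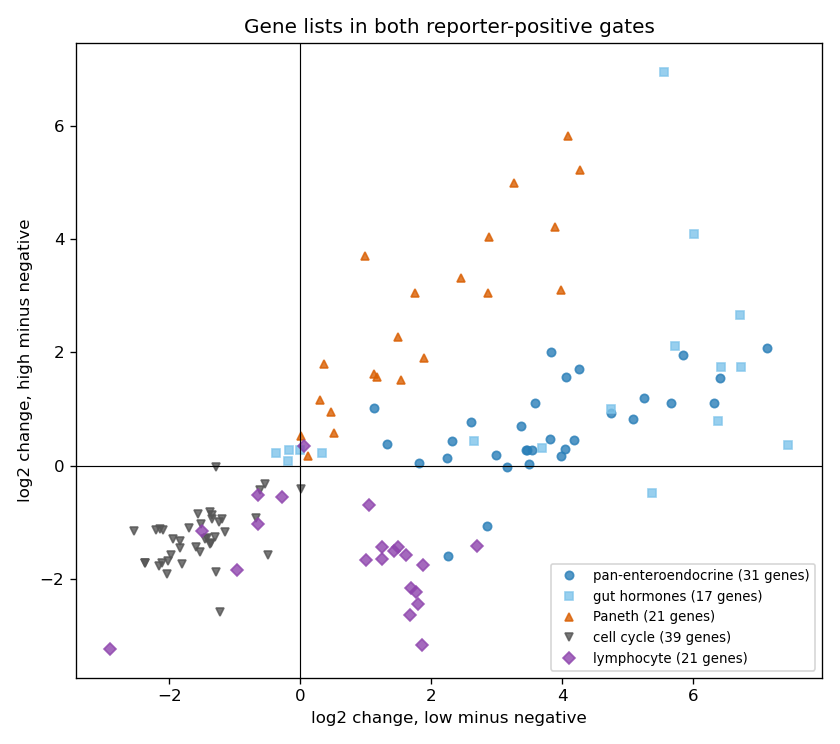
Log2 change of list members in low minus negative cells (horizontal axis) and in high minus negative cells (vertical axis), 1 point per gene. Pan-enteroendocrine genes spread along the horizontal axis. Of 21 Paneth genes, 11 were called higher in low cells and 13 in high cells. Some lymphocyte genes such as Cd3g lie right of 0 and below it. Of 21 lymphocyte genes, 9 were called higher and 2 lower in low cells.

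The genes of the planar cell polarity and non-canonical Wnt list showed almost no called change. Of 43 measured genes, 31 lay above background. By limma 0 passed in low against negative cells and 0 in high against low cells, where 1188 and 978 of all 19938 genes passed. In each comparison 3 members had an unadjusted p under 0.05, as did 3683 and 4502 of all 19938 genes. The counts adjusted over the list alone were also 0. Without high replicate 1, 1 gene was higher and 1 lower in high against low cells. In high against negative cells only Jun, which is also in the list of dissociation genes, rose, by 0.94 ± 0.18 (adjusted p = 0.0359), and 1 gene rose adjusted over the list alone. In that comparison 939 of all 19938 genes passed. An unadjusted p under 0.05 was seen for 5 members of the list and for 4430 of all 19938 genes. The call of Jun was lost in 3 alternative fits (adjusted p = 0.0538, 0.0573 and 0.0739) and without negative replicate 1, negative replicate 2 or high replicate 2 (0.202, 0.209 and 0.0518). The list test gave a camera adjusted p = 0.253, 0.0725 and 0.52 in low against negative, high against negative and high against low cells. In high against negative cells it passed without high replicate 2 (adjusted p = 0.0451).

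Some genes were called in both comparisons with negative cells. In both positive gates 92 genes rose, where independent lists of these sizes give 9.29, and 252 fell, where independent lists give 16.96. In 20 simulations without effects that shared the negative arrays, the highest overlap was 0, which sets no bound because almost no gene is called without effects. Across 12891 genes above background the log2 changes correlated at 0.49, against 0.50 in those simulations, and their covariance was 0.27, against 0.04. The simulations gave all gates equal means, so the difference of 0.23 lies beyond the noise of the shared negative arrays only. It does not tell a change shared by low and high cells from genes particular to the negative gate. A difference of correlations does not estimate a shared effect. The part of the excess of called genes that comes from the shared negative arrays was not estimated. A further 43 genes rose in low cells and fell in high cells, where independent lists give 22.8, and 0 fell in low cells and rose in high cells, where independent lists give 6.92.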

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

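Of the tests in this part, only that of the later lymphocyte list was set before its result was seen. The others were chosen after. The criterion for a single Paneth share was tightened for a time after its value was seen and is used here in its first form, and the criterion for the signal ceiling was made stricter after its value was seen.

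Probe sets that name several genes or no gene were outside the comparisons and carried signal. Among those with several symbols, 26 were called in low against negative, 21 in high against negative and 24 in high against low cells, in a fit over all 35556 probe sets. Among unlisted probe sets, 96, 64 and 66 were called. All 6 alpha-defensin probe sets with several symbols were higher than in negative cells in both gates, by a median of 1.77 in low and 2.04 in high cells.

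Some T cell genes were higher in low cells and lower in high cells. A smaller share of the main epithelial cells would raise every other cell type alike. The median change of Jchain, Igkv10-96, Mcpt1 and Mcpt2 in low cells was -2.99. Against the background level, where an array lay below it, the median was -2.80. These genes are among the 6 largest decreases of the same comparison. Their median was therefore bound to be negative and cannot decide the question. It shows only that these plasma and mast cell genes did not rise with the T cell genes. Lymphocytes sorted with the low cells are a candidate explanation. A further 26 lymphocyte genes, 0 of them in an earlier list and 25 above background in negative cells, had a median change of 1.32. At least 1 was set beforehand. By limma 13 of the 26 were called higher and 0 lower. The list was set after the first lymphocyte list had risen on the same arrays. Genes expressed in the same cells would move together, so reaching that value adds little to the first list. Ccl5 and Cd7, markers of the first list with high signal, averaged 12.59 and 12.01 in low, 11.58 and 10.12 in negative and 9.92 and 8.37 in high cells, and the labels name no gate other than reporter level. A change of these genes within epithelial cells was not tested.

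Paneth genes were raised to different degrees in low cells relative to high cells: for Sox9 the low gate held 0.116 of the linear excess of the high gate, and for Lyz1 0.992. Below a high-gate level of 12 on the log2 scale the largest share was 12.5 times the smallest. Among the 6 genes also above 8 it was 7.77 times the smallest. The criterion for Paneth cells like those of the high gate, mixed in at a single share, was therefore not met. That criterion takes the signal as linear and the other low cells as level with negative cells. Neither was tested, so a single share is not excluded. Among those 6 the low gate's level relative to the high gate still differed 4.99-fold with nothing subtracted for negative cells. A ceiling of the array signal cannot be told apart from other causes for the brightest genes: the share was higher at higher levels over 13 genes (Spearman's rho 0.57), but also among the 6 away from the ceiling (0.77), and levels of different probe sets have no common scale. A distinct Paneth-like state in the low gate was not tested.

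The Flattop transcript showed no called difference although the gates were set by its reporter. The 95% interval of high minus negative extended 0.84 on either side, so a 1.5-fold change could have been missed, and too few arrays cannot be told apart from a transcript that does not follow the reporter protein.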

How the results depend on the processing

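The alternatives were fixed before the data were examined, except the counts of list members and the fits of genes and lists named outside the rule, added after. For low against negative, high against negative and high against low cells, the counts with adjusted p under 0.1 were 1914, 1817 and 1771, with unadjusted p under 0.01 and 1.5-fold 1944, 1898 and 1883, and with array weights 2150, 620 and 607. With only the groups compared they were 1761, 561 and 499, and high against negative gave 621 after quantile normalization. Looser thresholds call more genes by construction, and the cause of the other shifts was not tested. Over genes above background, the SD of the difference between replicates was 0.63 in the high, 0.40 in the negative and 0.45 in the low gate. The main fit assumes an equal spread in all gates, so its counts in every comparison rest on that assumption. The spread of the high gate also enters low against negative, whose count went from 1188 to 1761 with only the groups compared. Without 1 array, which leaves a lone array assumed to vary like the others, the counts ranged from 187 to 565, from 13 to 1919 and from 381 to 1739. Of 3535 values of named genes outside the left-out arrays, 3309 kept their side of the threshold, 99 lost it, 127 gained it and 0 changed direction; of 1292 with an array left out, 333 lost it. Of 4827 named values, 22 that were called under neither setting changed sign. The test with an estimated correlation ended 34 list calls. The correlation value alone does not account for this. Ribosome biogenesis genes had an estimate of 0.0097, against the preset 0.01, and stem cell markers one of -0.0292. Their camera adjusted p in low against negative cells still went from 6.92e-06 and 4.13e-05 to 0.0592. Of the 15, 12 and 11 calls in low against negative, high against negative and high against low cells, 3, 0 and 1 stayed. Other alternatives ended 17. The median change over all genes moved by less than 0.1 under both scalings. With the replicate number as a replicate block the counts were 1298, 1065 and 965. The deviations of same-numbered arrays correlated at 0.10, 0.10 and 0.08 between gates, and enterocyte genes were lower on replicate 2 in every gate. These values do not settle whether the numbers pair the arrays. The labels do not say so, and the main fit does not pair them. The fit over all 18 arrays and the lineage alternatives were not run. Genes near the background level of 4.23 give compressed changes.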

Other observations

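The lists of excitable cells, detoxification and MHC class II were chosen after single members had been seen, so their tests describe and do not establish a direction. Their camera p-values were adjusted among the later lists alone, not over the 23 lists fixed before, so the adjusted p of both sets cannot be compared. The cilia list was fixed before the data were examined. Some genes of excitable cells were higher in low cells: of 21 ion channel and synaptic vesicle genes, 11 rose over negative cells, or 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.26e-13, and adjusted p = 0.0194 with an estimated correlation). The irritant receptor gene Trpa1 rose by at least 4.54, Scn3a by at least 3.21 and Cacna2d1 by at least 2.58 on the log2 scale, none above background in negative cells. Called ion channel and vesicle genes numbered 6 (without negative replicate 1), 7 (without negative replicate 2), 9 (without low replicate 1) and 10 (without low replicate 2). In high against negative cells 0 of the 21 passed by limma, also 0 adjusted over the list alone. An unadjusted p under 0.05 was seen for 3 of them and for 4430 of all 19938 genes. The list test passed upward (camera adjusted p = 0.00452, but adjusted p = 0.105 with an estimated correlation). Dim genes lay higher in the high gate: the median high minus negative change was 0.10 over all genes and -0.07 above background. The list test does not separate this shift from a change of the listed genes.

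Of 22 carboxylesterase, glutathione transferase, cytochrome P450 and glucuronosyltransferase genes, 9 fell in low cells and 7 in high cells, or 13 and 12 adjusted over the list alone (camera adjusted p = 1.68e-09 and 1.61e-10, but adjusted p = 0.133 and 0.105 with an estimated correlation). Mgst1 fell by 2.80 in low and by 1.94 in high cells. Of 7 MHC class II genes, 3 fell in each gate, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.000525 and 1.65e-05, but adjusted p = 0.133 and 0.105 with an estimated correlation). Cd74 fell by 1.28 and 1.51. The call of Cd74 in low cells was lost without negative replicate 1 (adjusted p = 0.0765), negative replicate 2 (adjusted p = 0.13), low replicate 1 (adjusted p = 0.0975) or low replicate 2 (adjusted p = 0.0838). The calls of Mgst1 and Cd74 in high cells were lost without negative replicate 1 (adjusted p = 0.11 and 0.106) or negative replicate 2 (adjusted p = 0.143 and 0.14). Called detoxification and MHC class II genes numbered in low cells 1 and 0 (without negative replicate 1), 1 and 0 (without negative replicate 2), 9 and 0 (without low replicate 1) and 1 and 0 (without low replicate 2). Called detoxification and MHC class II genes numbered in high cells 0 and 0 (without negative replicate 1), 0 and 0 (without negative replicate 2), 8 and 3 (without high replicate 1) and 2 and 4 (without high replicate 2).

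Genes of motile cilia, the structure that Flattop helps to build, were measured partly at background, with 18 of 37 above it. Of the 37, 3 rose in low cells, Fam183b by 3.82 ± 0.40, Rfx3 by 2.19 ± 0.31 and Dnah9, not above background in negative cells, by at least 1.41, or 4 adjusted over the list alone (camera adjusted p = 0.0245, but adjusted p = 0.328 with an estimated correlation). The calls of Rfx3 and Dnah9 were lost without negative replicate 1 (adjusted p = 0.0944 and 0.0919). The call of Dnah9 was lost without negative replicate 2 (adjusted p = 0.0527) or low replicate 1 (adjusted p = 0.0567). The call of Rfx3 was lost without low replicate 2 (adjusted p = 0.0759). Called cilia genes numbered 1 (without negative replicate 1), 2 (without negative replicate 2), 2 (without low replicate 1) and 2 (without low replicate 2). The list test was lost without low replicate 2 (adjusted p = 0.0718). In high against negative cells 0 passed by limma, also 0 adjusted over the list alone. An unadjusted p under 0.05 was seen for 3 of the 37 and for 4430 of all 19938 genes. The list test passed upward (camera adjusted p = 0.00962, but adjusted p = 0.302 with an estimated correlation). With 18 of 37 genes above background, this test does not separate a change of cilia genes from the higher values of dim genes in the high gate.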
